A study of Mus musculus with 12 samples.

How the data were processed

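RNA was sequenced from the ventral hippocampus of 12 male C57BL/6J mice, 3 in each of 4 groups. Per the labels' protocols, naive mice were 8 weeks old and restraint lasted 2 hours a day for 14 days. RNA was extracted with Trizol, and 1.3 µg of total RNA went into each library, made with the NEBNext Ultra II Directional kit, which keeps strand, per the same labels. The sample titles give 14 days of voluntary wheel running for both running groups, while the protocol text gives 4 weeks. Both are reported here because nothing in the sources used here settles which holds.

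The authors deposited 1 table per mouse, with whole-number estimated counts for 33299 RefSeq transcripts under 23183 gene symbols, not normalized. Reads of a gene were taken to be divided among its isoforms in these deposited counts, which was not tested. For that reason they were treated as estimates and not as direct read counts. Per the submitters' processing notes, TopHat and the mouse genome build mm10 were used. The counting program, its strand setting and the annotation release are not given in the sources used here, so reads of overlapping genes, antisense partners and near-identical copies cannot be told apart with certainty. All deposited values were whole, so rounding to whole numbers changed none. No entry was blank or held a total, and no column of values was left out. Totals ran from 9323607 to 15707516 counts per library.

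Transcript values were summed per gene symbol. That choice was made after the tables had been inspected, and the tests on transcripts as deposited are given as an alternative. Genes with too few counts were removed with filterByExpr at its default minimum count of 10, which left 14541 genes. Libraries were scaled with TMM factors, which lay between 0.97 and 1.039. Differences were tested with edgeR's quasi-likelihood F test in 1 fit of all 12 libraries with 8 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with calls made at an adjusted p under 0.05. The estimated biological coefficient of variation was 15.7%. Every adjusted p of a gene is from this edgeR test unless another tool is named, and errors beside log2 fold changes are standard errors derived from the F statistic. Means of CPM (counts scaled to library size with the TMM factors) are given with the SD over 3 mice. Counting error is the smaller part of the spread for genes with many counts at these depths. That does not hold for genes with few counts, such as Usp18 with 5, 2 and 2 counts in SS mice 18, 19 and 21. A count of 0 allows up to 3 counts, which is 0.191 to 0.322 CPM depending on the library. This floor covers counting error only, because amplified reads without molecular identifiers are not independent molecules.

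Before the data were examined, 36 gene lists for pathways, hippocampal cell types and neighbouring tissues were fixed, and 34 of them had the minimum of 5 measured members. They were tested with limma's camera, two-sided, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and adjusted over the 34 lists within each comparison. In the 4 main comparisons none of the list calls held when the correlation was estimated from the data, so the adjusted p from that version is given beside each list. The rotation test fry, which asks whether the genes of a list move on balance in 1 direction, was the other alternative. Genes to be named were also fixed by rule before the data were examined. For each main comparison these were the 10 higher and 10 lower genes with the smallest p among those called with groups that did not overlap, or the 5 with the smallest p in a direction where fewer than 5 were called. They also included the 4 members with the smallest p of every called list, up to 2 called members of every other list, and always Bdnf, Nr3c1, Nr3c2, Fkbp5, Crhr1, Fos and Ttr. Symbols of predicted genes, microRNAs and small nucleolar RNAs were left out. The report gives a selection of these, and some named genes are not reported here.

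A stress axis was built from the C and SS mice alone. The 500 genes with the smallest p of a fit of these 2 groups were taken, and each mouse was placed by the signed sum of its log2 differences from the C mean, scaled so that C averaged 0 and SS averaged 1. SES and SER positions were compared with an exact two-sided permutation test. Comparisons that share a group share its chance values, so covariances of fold changes were set beside 100 simulations of unchanged groups and beside the covariance that the spread of the shared SS libraries gives. Calls shared by SES and SER against C were set beside 30 simulations of unchanged groups, added after the data had been seen. Coordinates are from the RefSeq gene table of the mm10 assembly, matched by transcript identifier and counted from 1.

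Alternatives covered DESeq2 size factors, upper-quartile factors, no filter and a stricter filter (a CPM of 1 in 3 samples), the DESeq2 Wald test, limma-voom, a fit of only the 2 groups compared, other thresholds, a choroid plexus covariate, 1 surrogate variable from svaseq, and each mouse left out in turn. Alternatives added after the data had been seen left out SS mice 19 and 21, or C mouse 2 and SS mouse 18, corrected for GC content and transcript length with a smooth trend per library, used the level of 8 nuclear-retained long noncoding RNAs as a covariate, tested transcripts, or left out 4 genes at 0 in SER. GC content and length were known for 98.9% of the genes tested.

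The tests were tested on simulated data drawn from the real means, dispersions and library sizes, with 100 genes changed 1.5-fold and 100 changed 2-fold. For SS against C, 28% of the 1.5-fold and 61% of the 2-fold changes were recovered among 14435 genes, with 3 false calls. For SES against SS the shares were 22% and 61% among 14427 genes with 2 false calls, for SER against SS 26% and 60% among 14428 genes with 8 false calls, and for SES against SER 28% and 64% among 14444 genes with 10 false calls. A simulated shift of the ribosomal protein list was called in each of these 4 comparisons, and of the lists that were not shifted 1 was called for SES against SS and 0 in the other comparisons. Simulated genes were drawn independently of each other, so these list calls do not test the preset correlation. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0 and matplotlib were used.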

Results

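Gene expression was measured by RNA sequencing in the ventral hippocampus, the part of the hippocampus tied to emotional behaviour, of 12 mice. The groups were unstressed controls (C), sedentary mice that were susceptible to chronic restraint stress (SS), and stress-susceptible mice with access to a running wheel whose behaviour improved (effective responders, SES) or did not improve (ineffective responders, SER), with 3 mice in each. Restraint was applied on 14 days for 2 hours a day. Wheel running lasted 14 days according to the sample titles and 4 weeks according to the protocol. The library totals were 10612290, 14041951 and 11774367 counts in C and 10201269, 12277527 and 11413840 in SS. They were 15707516, 14916421 and 13378597 counts in SES and 12714883, 11943969 and 9323607 in SER.

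The first comparison asked how the hippocampus of stress-susceptible mice differed from that of unstressed controls. Some genes induced by glucocorticoids were higher in SS. Hif3a, a hypoxia-inducible factor subunit (mm10, chromosome 7, 17030993 to 17062427), had 15.8 ± 2.02 CPM in SS and 5.92 ± 1.72 in C (SD, n = 3), a log2 fold change of 1.42 ± 0.21 (adjusted p = 0.0223). The receptor tyrosine kinase gene Mertk (0.53 ± 0.12, adjusted p = 0.0244), the zinc finger factor Zbtb16 (0.49 ± 0.12, adjusted p = 0.0285) and the mTOR inhibitor Ddit4 (0.60 ± 0.18, adjusted p = 0.0488) were also higher. Of the 20 measured members of the glucocorticoid-induced list, 4 rose and 16 were not called, and 5 rose and 1 fell when adjusted over the list alone. The list median was 0.42 (camera adjusted p = 0.00954), with an adjusted p = 0.871 with an estimated correlation. Against the C mean the list stood at 0.69, 0.08 and 0.33 in SS mice 18, 19 and 21 and at −0.10, −0.20 and 0.37 in C mice 2, 8 and 12. Without SS mouse 18 that median was 0.16 and the list was no longer called (adjusted p = 0.49). It was also not called without C mouse 2 (0.33, adjusted p = 0.0629) or C mouse 8 (0.28, adjusted p = 0.0636). The receptor gene Nr3c1 had a log2 fold change of −0.42 ± 0.14 (adjusted p = 0.0674) and Fkbp5 of 0.43 ± 0.22 (adjusted p = 0.216), neither of which passed. The clock gene Per1 rose by 0.78 ± 0.17 on the log2 scale (adjusted p = 0.0233), 1 of 2 members called among 17 circadian clock genes, a list that was not called (camera adjusted p = 0.623).

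Genes of mitochondrial respiration and of the ribosome were lower in SS. Of 61 nuclear-encoded oxidative phosphorylation genes, 30 fell and 31 were not called, and 44 fell when adjusted over the list alone. They included the cytochrome c oxidase subunits Cox7b (−0.61 ± 0.10; 170.5 ± 20.1 CPM in SS and 260.5 ± 11.5 in C, SD, n = 3) and Cox7c (−0.59 ± 0.10), the complex III subunit Uqcrb (−0.61 ± 0.11) and the complex I subunit Ndufs4 (−0.56 ± 0.10), each at an adjusted p of 0.0223. The list median was −0.37 (camera adjusted p = 2.12e-19), with an adjusted p = 0.72 with an estimated correlation. Of 50 cytosolic ribosomal protein genes, 32 fell and 18 were not called, and 44 fell when adjusted over the list alone. Rps24 (−0.62 ± 0.11), Rpl5 (−0.52 ± 0.09) and Rpl23 (−0.56 ± 0.10) were among them. Ribosomal protein genes have many near-identical copies in the genome, so the division of their reads is uncertain. Their median was −0.43 (camera adjusted p = 2.12e-19), with an adjusted p = 0.72 with an estimated correlation. Fry also called both the oxidative phosphorylation and the ribosomal list (fry adjusted p = 0.0465 for the latter). After a correction for GC content and transcript length these medians were −0.11 and −0.16, and with SS mouse 18 as the only SS mouse they were −0.21 and −0.27.

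The glycine receptor subunit Glrb (−0.52 ± 0.08), the interneuron calcium-binding protein Pvalb (−0.78 ± 0.13) and the neuronal calcium sensor Vsnl1 (−0.71 ± 0.11) fell, each at an adjusted p of 0.0223. The NMDA receptor subunits Grin1 (0.52 ± 0.13, adjusted p = 0.0285) and Grin2c (0.47 ± 0.12, adjusted p = 0.0289) rose. Before scaling, Grin1 had 2631, 2502 and 2483 counts in C mice 2, 8 and 12. In SS mice 18, 19 and 21 it had 2550, 4302 and 3770. Against the C mean the glutamate receptor list stood at −0.28, 0.33 and 0.36 in these SS mice, with opposite signs within the group. Of 20 GABA genes 3 fell (3 when adjusted over the list alone; camera adjusted p = 0.117), and of 21 glutamate receptor genes 5 rose (5 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.103), so neither list was called. The growth factor Igf1 fell by 0.56 ± 0.13 on the log2 scale (adjusted p = 0.0285), and Bdnf had a log2 fold change of −0.25 ± 0.10 that did not pass (adjusted p = 0.119). The chromatin gene H2afz, the cytochrome c gene Cycs and the guidance factor Sema3c were also among the 10 lower genes with the smallest p, and Pcdhga9, Zfp865, Tyk2, Ascc2, Rnf123, Med12, Slit1, Cc2d1a and Atxn2l joined Hif3a among the higher. Pcdhga9 shares exons with other genes of its cluster, so its reads are uncertain.

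**Figure D1:**
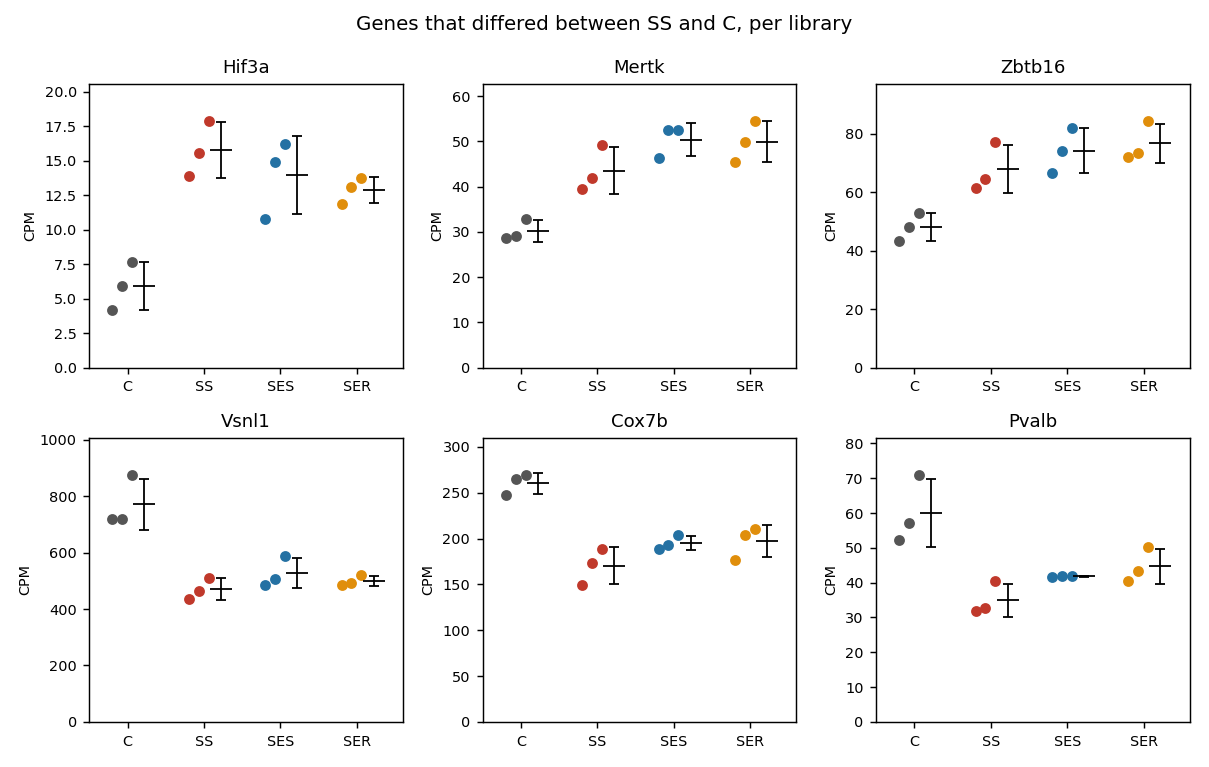
CPM (vertical axes, from 0) of 6 genes in the 3 mice of each group, with points for mice and a bar with whiskers for the mean ± SD. Points are sorted by value, and Hif3a, Mertk and Zbtb16 lay higher and Vsnl1, Cox7b and Pvalb lower in every SS mouse than in every C mouse.

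Among cell type lists, dentate gyrus granule cell markers were higher in SS, with a median of 0.51 (camera adjusted p = 0.00266; adjusted p = 0.72 with an estimated correlation). Of 13 members 2 were called, 7 when adjusted over the list alone, C1ql2 (0.75 ± 0.18, adjusted p = 0.0282) and Rfx3 (0.59 ± 0.15, adjusted p = 0.0344). Oligodendrocyte and myelin markers were lower, with 1 of 18 called (1 when adjusted over the list alone), the myelin gene Opalin (−1.01 ± 0.24, adjusted p = 0.0285). Their median was −0.37 (camera adjusted p = 0.0105; adjusted p = 0.871 with an estimated correlation). The myelin median turned to 0.35 with SS mouse 18 as the only SS mouse, a call in the opposite direction (adjusted p = 0.0237), and the list was not called without SS mouse 19 (−0.15, adjusted p = 0.0947), SS mouse 21 (−0.14, adjusted p = 0.155) or C mouse 2 (−0.35, adjusted p = 0.064). Interferon response genes had 2 of 23 called lower (2 when adjusted over the list alone), Ifit1 and Usp18, and a median of −0.39 (camera adjusted p = 0.0116; adjusted p = 0.87 with an estimated correlation), a call lost without C mouse 2 (−0.34, adjusted p = 0.064). With SS mouse 18 as the only SS mouse, which is then assumed to vary as the mice of the other groups do, the dentate and interferon medians were 0.32 and −0.32 and neither list was called (adjusted p = 0.176 and 0.192). Endothelial and mural markers had 2 of 18 called lower (2 when adjusted over the list alone), Itm2a and Acta2, and a median of −0.19 (camera adjusted p = 0.0439; adjusted p = 0.871 with an estimated correlation). That call was lost without SS mouse 18 (−0.04, adjusted p = 0.564), C mouse 2 (−0.01, adjusted p = 0.244) or C mouse 8 (−0.25, adjusted p = 0.0766), or with the choroid plexus level as a covariate (−0.19, adjusted p = 0.0634), and the myelin call with the nuclear RNA level as a covariate (0.05, adjusted p = 0.839). The endothelial median was −0.55 with SS mouse 18 as the only SS mouse and −0.45 with the nuclear RNA covariate. Without C mouse 2 and SS mouse 18 it turned to 0.15. Camera called these 7 lists, and 3 lists without C mouse 2 and 11 without C mouse 12.

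In all, 1430 genes differed between SS and C, 757 higher and 673 lower. Of all genes tested, 3908 (26.9%) had groups that did not overlap, which chance gives for 10%. The number of called genes rested on single libraries. In edgeR's test it was 0 without C mouse 8, without SS mouse 19 or without SS mouse 21, 78 without C mouse 12, 848 without C mouse 2 and 3797 without SS mouse 18. It was also 0 in a fit of only the 2 groups, after the GC content and length correction and with the nuclear RNA level as a covariate, while 4105 genes had an unadjusted p under 0.05, DESeq2's Wald test called 2219 and limma-voom 1209. The SS libraries differed among themselves. Across genes, log2 CPM of SS mice 19 and 21 correlated at 0.991 with each other and at 0.955 and 0.951 with SS mouse 18, and genes are not independent replicates. The nuclear noncoding RNA Malat1, chosen after its values were seen, stood at 505 CPM in SS mouse 18 and at 3761 and 5257 CPM in SS mice 19 and 21, against 505.5, 262.8 and 489.2 CPM in C. The choroid plexus gene Ttr stood at 5095 CPM in SS mouse 18 and at 5.725 and 12.06 CPM in the other SS mice, and at 3546 CPM in C mouse 2 against 2.783 and 20.1 CPM in the other C mice.

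**Figure D2:**
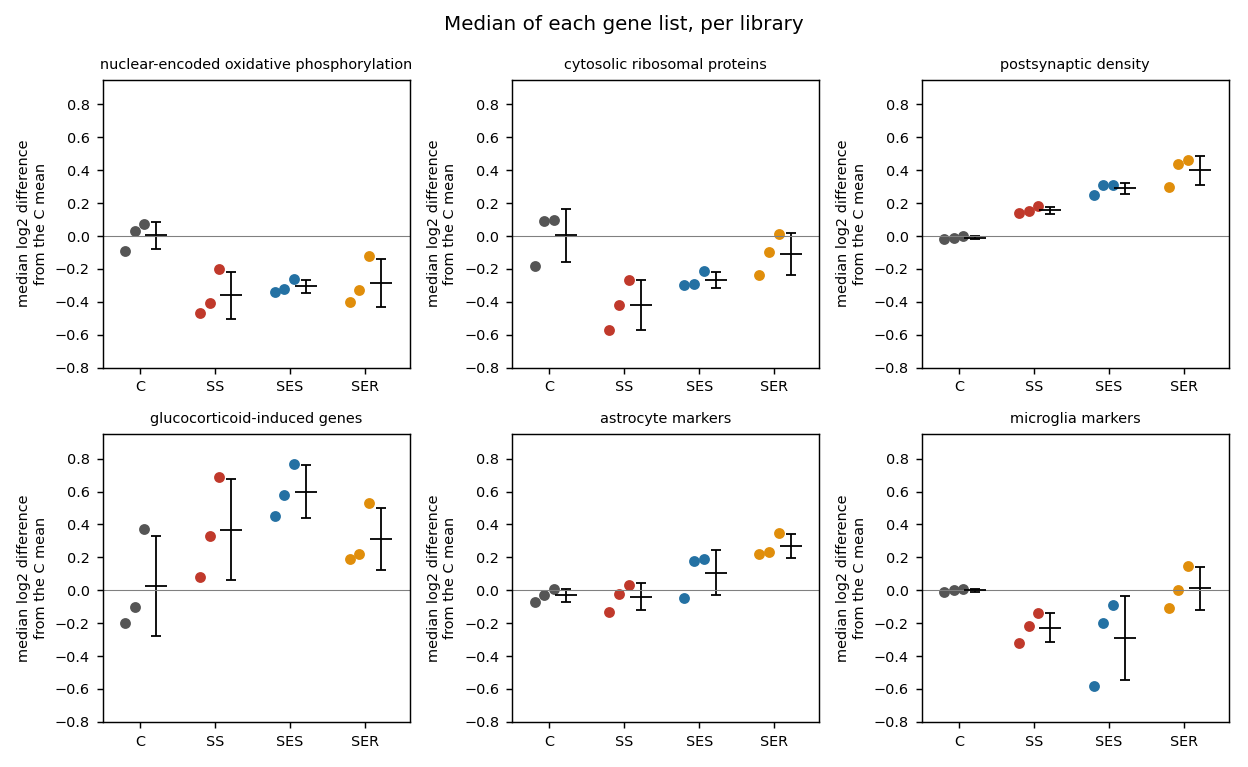
Median log2 difference from the C mean (vertical axes) over the members of 6 gene lists, with points for mice and a bar with whiskers for the mean ± SD of 3 mice. Points are sorted by value, and oxidative phosphorylation medians lay between −0.47 and −0.12 in the 9 stress-exposed mice and between −0.09 and 0.07 in C.

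The comparison of SES with SS asked what effective running went with. No gene passed in edgeR's test. There were 1310 genes with an unadjusted p under 0.05, and DESeq2's Wald test called 17 and limma-voom 0. The smallest adjusted p was that of Pou3f1, a POU-domain transcription factor of CA1 neurons, at 101.2 ± 7.23 CPM in SES and 58.7 ± 7.87 in SS (SD, n = 3; log2 fold change 0.79 ± 0.12, adjusted p = 0.177). Fam107a, an actin-associated stress-responsive gene, had a log2 fold change of 0.62 ± 0.12, Bdnf of 0.40 ± 0.10, the metallothionein Mt2 of 0.81 ± 0.18 and the immediate early gene Egr1 of 0.65 ± 0.22, each at an adjusted p of 0.524. Without SS mouse 18 the same test called 1283 genes, and without SS mouse 19 it called 1.

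Camera called 10 lists in SES against SS, all higher, in none of which a single gene passed over all genes tested. When adjusted over the list alone, 3 glucocorticoid-induced genes, 2 GABA genes, 1 astrocyte marker and 1 CA1 and subiculum marker were higher, and 0 genes of the other 6 lists passed. CA1 and subiculum markers had a median of 0.37 (adjusted p = 9.94e-05; adjusted p = 0.293 with an estimated correlation) and 13 of 15 positive members, with Spink8 at 0.87 ± 0.29 and Man1a at 0.61 ± 0.21. The postsynaptic density list had a median of 0.15 (adjusted p = 0.0266; adjusted p = 0.293 with an estimated correlation), with Homer1 at 0.43 ± 0.12 and Dlgap1 at 0.27 ± 0.09. It was the list that fry also called (adjusted p = 0.0151), and its camera call was lost without SS mouse 18 (0.12, adjusted p = 0.13) or with SS mouse 18 as the only SS mouse (0.14, adjusted p = 0.198). Glucocorticoid-induced genes had a median of 0.24 (adjusted p = 0.000138) and ribosomal protein genes of 0.14 (adjusted p = 4.88e-07), both with an adjusted p = 0.755 with an estimated correlation. With SS mouse 18 as the only SS mouse these medians were −0.15 and 0. Without C mouse 2 and SS mouse 18 they were 0.597 and 0.225. Choroid plexus markers had a median of 0.42 (adjusted p = 2.88e-05; adjusted p = 0.755 with an estimated correlation). That median turned to −1.03 with SS mouse 18 as the only SS mouse. It was 4.55 without C mouse 2 and SS mouse 18, and 1.07 with the nuclear RNA covariate. Astrocyte markers (0.12), GABA genes (0.11), immediate early genes (0.29), neuropeptides (0.16) and oxidative phosphorylation genes (0.05) had camera adjusted p-values of 0.028, 0.0425, 0.0266, 0.041 and 0.0358, in that order. With an estimated correlation the first 4 had an adjusted p = 0.755 and the last an adjusted p = 0.783. The astrocyte call was lost without SS mouse 21 (0.03) or SES mouse 9 (0.08), and the GABA call without SS mouse 18 (0.10), SES mouse 9 (0.08) or SES mouse 12 (0.08). The immediate early call was lost without SS mouse 18 (0.06) or SES mouse 12 (0.20), and the neuropeptide call without SS mouse 18 (0.02) or SES mouse 9 (0.04). With SS mouse 18 as the only SS mouse the immediate early median was 0.65 and the neuropeptide median 0.84. The oxidative phosphorylation call was lost without SS mouse 19 (0.01), SS mouse 21 (0.05) or SES mouse 9 (0.03). With SS mouse 18 as the only SS mouse the oxidative phosphorylation list was called in the opposite direction (−0.08, adjusted p = 0.0179), the astrocyte median turned to −0.02 (adjusted p = 0.986), and the GABA list was not called (0.15, adjusted p = 0.0983). With the choroid plexus level as a covariate the astrocyte (0.07, adjusted p = 0.0878), GABA (0.06, adjusted p = 0.0573) and oxidative phosphorylation (0.01, adjusted p = 0.561) calls were lost, as was that of the choroid plexus list (0.10, adjusted p = 1). The GC content and length correction ended the GABA (0.03, adjusted p = 0.14) and oxidative phosphorylation calls (0.01, adjusted p = 0.602), and the nuclear RNA covariate the astrocyte (0.08, adjusted p = 0.0564) and oxidative phosphorylation calls (0.02, adjusted p = 0.37).

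The comparison of SER with SS asked what running went with where behaviour did not improve. Pou3f1 (chromosome 4, 124657646 to 124660655) rose to 112.3 ± 6.43 CPM from 58.7 ± 7.87 in SS (SD, n = 3; log2 fold change 0.94 ± 0.12, adjusted p = 0.00559). Sox9, a transcription factor of astrocytes (chromosome 11, 112782210 to 112787757), rose to 97.7 ± 2.54 CPM from 56.6 ± 4.52 (0.79 ± 0.11, adjusted p = 0.0179). Fam107a (chromosome 14, 8296270 to 8317607) rose to 1287 ± 28.3 CPM from 734 ± 118 (0.81 ± 0.12, adjusted p = 0.0366). The astrocyte glutamate transporter Slc1a2 (0.69 ± 0.12, adjusted p = 0.0709) and the synaptic scaffold Git1 (0.64 ± 0.10, adjusted p = 0.0547) did not pass. Pou3f1 was not called without SER mouse 6 (0.91, adjusted p = 0.0533), nor Sox9 without SS mouse 19, SS mouse 21, SER mouse 6 or SER mouse 20 (0.82, 0.72, 0.78 and 0.79; adjusted p = 0.0842, 0.168, 0.104 and 0.107). Fam107a was not called without SS mouse 19, SS mouse 21, SER mouse 6, SER mouse 19 or SER mouse 20 (0.72, 0.78, 0.81, 0.80 and 0.84; adjusted p = 0.271, 0.298, 0.137, 0.0714 and 0.156), nor without the 4 genes listed at 0 in SER (0.81, adjusted p = 0.0844). With the nuclear RNA level as a covariate Sox9 (0.77, adjusted p = 0.0835) and Fam107a (0.69, adjusted p = 0.0996) were not called. In a fit of only the 2 groups none of Pou3f1, Sox9 and Fam107a was called (0.94, 0.79 and 0.81; adjusted p = 0.0994, 0.0994 and 0.245), nor with SS mouse 18 as the only SS mouse (0.94, 0.73 and 0.58; adjusted p = 0.0884, 0.202 and 0.241).

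**Figure D3:**
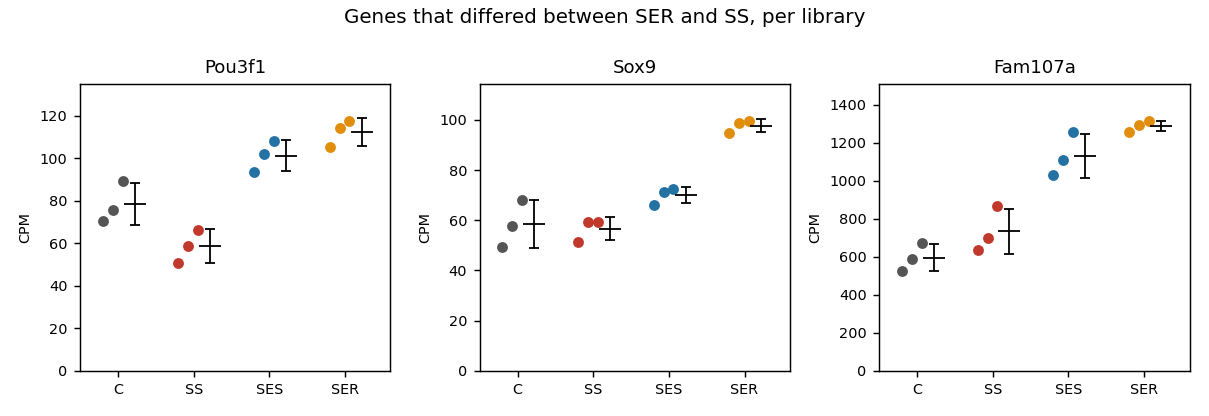
CPM (vertical axes, from 0) of Pou3f1, Sox9 and Fam107a in the 3 mice of each group, with points for mice and a bar with whiskers for the mean ± SD. Points are sorted by value, and all SER mice lay above all SS mice for the 3 genes.

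The other 4 genes called in SER against SS were listed at 0 in all 3 SER mice and had counts in all 9 other mice. Lars2, the mitochondrial leucyl-tRNA synthetase (chromosome 9, 123366927 to 123462675), had 56579 to 274209 counts in the other mice. Zc3h7a (chromosome 16, 11136594 to 11176393) had 220 to 546 counts, and Cmss1 (chromosome 16, 57301999 to 57606867) and Filip1l, which lies within it (57353277 to 57572804), had 67 to 145 and 23 to 63 counts. Lars2 was not called by limma-voom in SER against SS (−17.87, adjusted p = 0.071). Filip1l was not called in edgeR's fit of only the 2 groups (−7.94, adjusted p = 0.0994). Altogether edgeR called 7 genes, 3 higher and 4 lower, and DESeq2's Wald test called 558. Without SS mouse 18 edgeR called 2434 genes, and without SER mouse 6 it called 4.

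Camera called 8 lists in SER against SS, all higher. Astrocyte markers had a median of 0.30 (adjusted p = 2.6e-06; adjusted p = 0.241 with an estimated correlation), with Sox9 called among 15 members and 9 higher when adjusted over the list alone. CA1 and subiculum markers had a median of 0.60 (adjusted p = 0.000108; adjusted p = 0.241 with an estimated correlation), with Pou3f1 called among 15 and 5 higher when adjusted over the list alone. The postsynaptic density list had a median of 0.30 (adjusted p = 0.000244; adjusted p = 0.0626 with an estimated correlation), with Camk2a at 0.41 ± 0.09 and Dlgap1 at 0.40 ± 0.09, and 9 of 20 higher and 1 lower when adjusted over the list alone. Fry called these 3 lists (adjusted p = 0.0189, 0.0191 and 6.15e-05). Ribosomal protein genes had a median of 0.32 (adjusted p = 3.78e-17), with 32 of 50 higher when adjusted over the list alone, microglia markers of 0.18, GABA genes of 0.19 and oxidative phosphorylation genes of 0.07 (adjusted p = 0.00777 for each), and immediate early genes of 0.35 (adjusted p = 0.0151). These 5 had an adjusted p = 0.866 with an estimated correlation, and 3, 2, 0 and 0 members of the last 4 were higher when adjusted over the list alone. The microglia call was lost without SS mouse 18 (0.20) and the GABA call without SS mouse 18 (0.18) or SER mouse 20 (0.13). The immediate early call was lost without SS mouse 18, SER mouse 6 or SER mouse 20 (0.17, 0.30 and 0.15), and the oxidative phosphorylation call without SS mouse 19 or SER mouse 19 (0.04 and 0.02), after the GC content and length correction (0.05, adjusted p = 0.0849) and with the nuclear RNA covariate (0.01, adjusted p = 0.878), and its median turned to −0.02 with SS mouse 18 as the only SS mouse (adjusted p = 0.129). With SS mouse 18 as the only SS mouse, the astrocyte and ribosomal medians were 0.145 and 0.156. Those of the CA1 and postsynaptic density lists were then 0.489 and 0.254, and those of microglia, GABA and immediate early genes 0.177, 0.214 and 0.716. For choroid plexus markers the median in the main fit was −1.40 while camera's direction was up (adjusted p = 0.532). In 20 of 136 list tests over the 4 comparisons, 0 of them called, median, mean and test differed in sign.

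The direct comparison of SES with SER asked whether effective and ineffective responders differed. Only the 4 genes listed at 0 in SER, Lars2, Zc3h7a, Cmss1 and Filip1l, passed in edgeR's test. DESeq2's Wald test called 6 genes, and 541 genes had an unadjusted p under 0.05. Sox9 stood at 70.0 ± 3.26 CPM in SES and 97.7 ± 2.54 in SER (SD, n = 3; log2 fold change −0.48 ± 0.11, adjusted p = 1), and Bdnf (0.05 ± 0.10), Nr3c1 (−0.23 ± 0.14), Fkbp5 (0.15 ± 0.22) and Fos (−0.61 ± 0.41) did not pass either.

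Camera called 9 lists between SES and SER. Lower in SES were microglia markers, with all 16 members negative and a median of −0.28 (adjusted p = 1.16e-07; adjusted p = 0.436 with an estimated correlation), such as Csf1r (−0.28 ± 0.10) and Cx3cr1 (−0.47 ± 0.18), and astrocyte markers, with 14 of 15 negative and a median of −0.22 (adjusted p = 1.11e-05; adjusted p = 0.436 with an estimated correlation). Ribosomal protein genes had a median of −0.17 (adjusted p = 4.15e-11; adjusted p = 0.77 with an estimated correlation) and postsynaptic density genes of −0.15 (adjusted p = 0.00396; adjusted p = 0.225 with an estimated correlation), the latter also called by fry (adjusted p = 0.0272). Higher in SES were meninges and fibroblast markers (median 0.47, adjusted p = 6.16e-05; adjusted p = 0.436 with an estimated correlation), such as Ogn (0.77 ± 0.21), and glucocorticoid-induced genes (0.28, adjusted p = 9.33e-05; adjusted p = 0.77 with an estimated correlation), such as Cdkn1a (1.00 ± 0.39) and Xdh (0.75 ± 0.26). Interferon response genes (0.26, adjusted p = 0.00396) and protein folding genes (0.16, adjusted p = 0.00396) were higher with an adjusted p = 0.77 with an estimated correlation. The interferon call was lost without SES mouse 10 (median −0.002, adjusted p = 0.474) or SER mouse 19 (0.26, adjusted p = 0.0985), and the folding call without SES mouse 10 (0.08) or SER mouse 20 (0.08). With the choroid plexus level as a covariate neither the interferon list (0.21, adjusted p = 0.13) nor the folding list (0.10, adjusted p = 0.0603) was called. Choroid plexus markers were higher by a median of 1.86 (adjusted p = 0.000731; adjusted p = 0.801 with an estimated correlation), and Ttr varied from 821.6 to 4700 CPM among SES mice and from 36.51 to 1080 CPM among SER mice. No member of these 9 lists passed over all genes tested. When adjusted over the list alone, 3 astrocyte markers were lower, 1 meninges marker and 1 interferon response gene were higher, and 0 genes of the other 6 lists passed.

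Against unstressed controls, 26 genes differed in SES (19 higher, 7 lower) and 173 in SER (124 higher, 49 lower). Hif3a (1.24 ± 0.21 and 1.13 ± 0.21) and Mertk (0.74 ± 0.12 and 0.73 ± 0.12) rose and Opalin (−1.90 ± 0.25 and −1.38 ± 0.25) fell in both, and Fam107a rose by 0.93 ± 0.12 and 1.11 ± 0.13. The SES number was 0 without SES mouse 12, 4 without C mouse 8, 7 without SES mouse 9 or SES mouse 10, and 16 without C mouse 12. The SER number was 6 without SER mouse 6, 11 without SER mouse 20, 20 without C mouse 12, 32 without C mouse 8 and 64 without C mouse 2. The 2 comparisons shared 14 higher and 6 lower genes, where independent lists would share 0.16 and 0.02. Unchanged groups set against the same C libraries shared 0 in each of 30 simulations. These simulations called a mean of 0.13 genes in SES and 0.2 in SER, so they could hardly share any. The simulations leave out real effects and the independent lists leave out the shared C libraries, so part or all of the excess may come from the shared C libraries.

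On the axis from C at 0 ± 0.108 to SS at 1 ± 0.22, SES mice stood at 0.658 ± 0.109 and SER mice at 0.543 ± 0.107 (SD, n = 3). The difference was 0.114 (exact two-sided permutation p = 0.2), in a design where the smallest possible p is 0.1. With 1 mouse left out in turn, the difference ran from 0.053 to 0.173. Axis genes were chosen on C and SS, so the distance of running mice from SS is biased and only SES and SER can be compared. A fit of only C and SS called 0 genes, so the axis genes are ranked by p and were not called there. SS mice 18, 19 and 21 stood at 0.748, 1.149 and 1.103, and SES mouse 12 at 0.757. The SS end of the axis therefore rests mainly on SS mice 19 and 21. Fold changes of SES and of SER against SS correlated at 0.665 across genes, and unchanged groups sharing the SS libraries gave 0.508 in simulations. Their covariance was 0.0734, against 0.0373 simulated and 0.0645 from the spread of the SS libraries. The covariance of SS against C with SES against SS was −0.0613 and with SER against SS −0.0806, where the spread of the SS libraries alone gives −0.0645. The excess over the SS spread was 0.0089 for the covariance of both running groups, 0.0032 for SES and −0.0161 for SER. Each changed sign when single SS mice were left out. The first was 0.1695 without SS mouse 18, −0.0728 without SS mouse 19 and −0.0704 without SS mouse 21. The SES value was −0.1537 without SS mouse 18, and the SER value was 0.0651 without SS mouse 19 and 0.0596 without SS mouse 21.

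**Figure D4:**
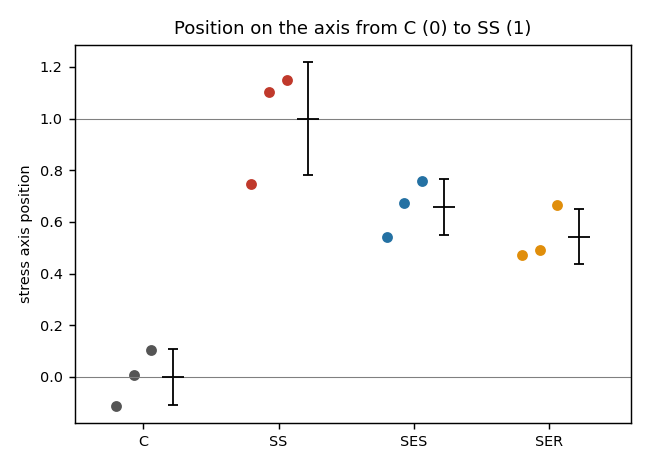
Position of each mouse on the axis from C (0) to SS (1) (vertical axis, no unit), with points for mice and a bar with whiskers for the mean ± SD of 3 mice. Points are sorted by value, and SES and SER mice lay between 0.471 and 0.757.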

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

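All tests in this part except the counts of other splits of the libraries were chosen after the results had been seen, and the bound of the linear fits was made stricter after the values had been seen. It was first 2 SE. A difference now counts as remaining only where the 95% interval leaves out 0 with each of 3 list summaries (medians centred on all mice or on C mice, and means). Under the first bound a difference remained in all 7 such tests, and in 4 of them it no longer counts as remaining. A remaining difference does not exclude an explanation, because a covariate or offset may correct only in part. Values are medians centred on all mice unless stated.

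Lars2 (adjusted p = 3.98e-05), Zc3h7a (6.9e-06), Cmss1 (6.9e-06) and Filip1l (0.000502) differed between effective and ineffective responders in the direct test of SES against SER and were listed at 0 in all SER libraries. Lower depth of those libraries is argued against, because the smallest count expected for any of the 4 genes in a SER library was 31.7. Partly lower expression in SER mice is argued against for Lars2. At the floor of 3 counts it would lie at least 39513-fold below its expected count in each SER library. For Zc3h7a, Cmss1 and Filip1l the smallest expected counts were 277.7, 82.7 and 31.7. The floor therefore leaves a large partial drop open for these genes. Of the 220 sets of 3 libraries, SER had 4 genes at 0 with at least 5 counts in each other library, and the highest of the other sets had 1. The genes at 3 places are at 0 together, Filip1l with the gene that contains it, while Txndc11, Rsl1d1 and Limd1 nearby had 120 to 797 counts in SER libraries (Tmem30c and Col8a1, also nearby, had 0 to 34 there and were low in some other libraries too). A candidate explanation is that the SER files were made with other gene models or filters, while a complete loss of expression in SER mice stays open, since it would give the same sum of 0 counts in the 3 libraries.

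The lower oxidative phosphorylation and ribosomal protein medians in SS against C were weighed against technical causes. The level of nuclear noncoding RNA was used as a covariate for the SS minus C difference of library medians. For oxidative phosphorylation the difference went from −0.368 to −0.248 ± 0.092 (95% interval −0.465 to −0.03). For ribosomal proteins it went from −0.41 to −0.268 ± 0.115 (−0.54 to 0.004). A difference remained for oxidative phosphorylation, but the covariate may correct only in part. In SS mouse 18 the nuclear RNA level was 0.725-fold that of C, while its list medians against the C mean were −0.20 and −0.27. The C mice lay between −0.09 and 0.07 for oxidative phosphorylation and between −0.18 and 0.10 for ribosomal proteins. A raised nuclear RNA level cannot account for the values of SS mouse 18, which is 1 library. In SS mice 19 and 21 it may account for part or all of each difference, and it stays open for both lists. After the GC content and length correction the differences were −0.114 ± 0.029 and −0.141 ± 0.056 (intervals −0.182 to −0.046 and −0.271 to −0.012). This correction and the nuclear RNA covariate were not combined. A bias of GC content and length may account for most or all of each difference, because a smooth trend may leave part of it. Genes of these kinds are known for short transcripts, so the correction can also remove a real change of them. A response to stress stays among the open explanations and was not tested apart from these.

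The lists that differed in the direct test of SES against SER had medians of −0.283 for microglia markers, −0.22 for astrocyte markers, −0.166 for ribosomal proteins, −0.154 for the postsynaptic density, 1.859 for choroid plexus, 0.47 for meninges, 0.281 for glucocorticoid-induced genes, 0.265 for interferon response and 0.158 for protein folding. With the choroid plexus level as a covariate, the SES minus SER difference of library medians went from −0.186 to −0.209 ± 0.081 (95% interval −0.4 to −0.019) for astrocyte markers and from −0.306 to −0.297 ± 0.137 (−0.622 to 0.028) for microglia markers. Both moved little and camera still called both lists, but with centring on C mice the astrocyte value was −0.161 ± 0.084 (−0.36 to 0.038), so choroid plexus tissue is not excluded for either list. For dilution of all cell types alike, the SES minus SER difference of microglia minus oligodendrocyte precursor markers was −0.245 ± 0.074 (−0.415 to −0.074), but with centring on C mice it was −0.217 ± 0.122 (−0.499 to 0.065), with −0.34, −0.43 and −0.70 in SES and −0.16, −0.51 and −0.14 in SER mice, so dilution stays open too. A difference in glia between responders also stays open, and the list calls ended with an estimated correlation. Other processing of the SER files, raised above for the genes listed at 0, would coincide with the SER group in every comparison with SER. Its effects on these lists, on other genes and on the stress axis could not be told apart from those of the group.

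The 10 splits of 6 libraries in each comparison are too few for a share under 0.05. Real gene counts, with the highest other split, were 1430 and 163 for SS against C (1 split as large, the real one included), 0 and 227 for SES against SS (10), 7 and 197 for SER against SS (2), 4 and 4 for SES against SER (2), 26 and 0 for SES against C (1), and 173 and 1 for SER against C (1). List counts were 7 and 12 (8 splits as large), 10 and 16 (7), 8 and 14 (8) and 9 and 14 (6) for the first 4 comparisons. The splits with 227 and 197 genes put SS mouse 18 with running mice, which points to a structure of the SS libraries.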

How the results depend on the processing

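The alternatives that left out SS mice 19 and 21 or C mouse 2 and SS mouse 18, corrected for GC content and length, used the nuclear RNA level, tested transcripts or left out the 4 genes at 0 in SER were chosen after the data had been seen. Without SS mice 19 and 21 the lone SS mouse is assumed to vary like the other groups. No paired analysis was made, because each sample was taken to be another mouse, also where groups share a mouse number. The alternatives for normalized values were not run, since the files hold counts. Of the single-gene and list values, and the counts for all stress-exposed mice, 4175 kept direction and side of the threshold, 701 lost it, 177 gained it and 56 reversed. Where no cause is given, the cause was not tested.

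Counts of genes are given for SS against C, SES against SS, SER against SS, SES against SER, SES against C and SER against C, where they left the range of 1.5 times. DESeq2's Wald test gave 2219, 17, 558, 412 (SES against C) and 784 (SER against C). Only the 2 groups compared gave 0 (SS against C), 3 (SER against SS), 160 and 281 (SES and SER against C). An adjusted p under 0.1 gave 2744, 104 (SER against SS), 47 and 609. An unadjusted p with a fold of 1.5 gave 382, 846, 181, 587 and 692 for the last 5. The choroid plexus covariate gave 2, 29, 83 and 435 for all but SS against C and SES against SER, and 1 surrogate variable gave 54 for SES against C. No filter gave 15 for SER against SS. Without SS mice 19 and 21 SS against C gave 0 and SER against SS 4. Without C mouse 2 and SS mouse 18 the counts were 3644, 1430, 2573, 929 and 796 for all but SES against SER. The GC content and length correction gave 0 (SS against C), 12 (SER against SS), 14 and 24, and the nuclear RNA covariate 0 (SS against C), 46 and 490. Without the 4 genes at 0, SER against SS gave 2 and SES against SER 0. Transcripts gave 2 (SS against C), 4 and 25.

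Leaving out 1 mouse gave 0 to 3797 genes for SS against C, 0 to 1283 for SES against SS, 4 to 2434 for SER against SS, 0 to 27 for SES against C and 6 to 173 for SER against C, and 3 to 11 lists for SS against C. The shared response, in excess of the SS spread, ran from −0.0728 to 0.1695, the reversal in SES from −0.1537 to 0.0867 and in SER from −0.1729 to 0.0651. Ranges of log2 values that crossed 0 were, for SS against C, −0.06 to 0.25 (Nr3c2), −0.27 to 0.21 (Crhr1) and −7.08 to 7.23 (Ttr); for SES against SS, −0.15 to 0.15 (Nr3c2), −0.37 to 0.02 (Crhr1), −0.03 to 0.79 (Fos), −0.05 to 8.23 (Ttr) and 0.023 to 0.236 (neuropeptides, where the test changed direction); for SER against SS, −5.09 to 5.48 (Ttr); and for SES against SER, −0.01 to 0.09 (Bdnf) and −0.03 to 0.24 (Fkbp5).

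Lists called, for SS against C, were 12 without SS mice 19 and 21 and 13 with the nuclear RNA covariate, and 17 for SER against SS without SS mice 19 and 21. An estimated correlation left 0 in each of the 4 comparisons, and fry 3, 1, 3 and 1. Without SS mice 19 and 21, the test reversed for myelin in SS against C (0.351), for astrocyte (−0.023), choroid plexus (−1.034), ribosomal (0), glucocorticoid (−0.149) and oxidative phosphorylation lists (−0.077) in SES against SS, and for oxidative phosphorylation in SER against SS (−0.023), and the reversed myelin, choroid plexus and SES against SS oxidative phosphorylation values passed the threshold. It also reversed for myelin with the nuclear RNA covariate (0.051), neuropeptides in SES against SS without C mouse 2 and SS mouse 18 (0.023), and choroid plexus with its own level as covariate (0.104 in SES against SS, 0.023 in SES against SER).

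Single genes that reversed without SS mice 19 and 21 were Col4a2 (−0.07), Aspa (0.02) and Ermn (0.11) in SS against C, Ccdc153 (−0.39), Otx2 (−0.35), Foxj1 (−0.63), Fkbp5 (−0.17), Crhr1 (0.17) and Ttr (−0.93) in SES against SS, and Fkbp5 (−0.31) in SER against SS. Without C mouse 2 and SS mouse 18 they were Ttr (−0.34 in SS against C, 5.48 in SER against SS), Nr3c2 (0.15) and Fos (−0.03) in SES against SS. The choroid plexus covariate reversed Ttr (−0.36 in SS against C, 0.55 in SER against SS), Crhr1 (0.02, SES against SS) and Fkbp5 (0, SES against SER). The surrogate variable reversed Ttr (−2.41 and 1.3) and Nr3c2 (0.17), the nuclear RNA covariate Ttr (−0.25, SS against C) and Fkbp5 (−0.07, SER against SS), limma-voom Ttr (1.08, SER against SS) and Nr3c2 (0.01), no filter Nr3c2 (0.01) and the stricter filter Nr3c2 (0), the last 3 in SES against SS.

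Depth limits genes near the floor of 3 counts, and the simulated recovery of 1.5-fold changes for these group sizes was 22% to 28%.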

Other observations

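All tests in this part were chosen after the data had been seen, except the count of splits, and the sterol synthesis list was drawn up after its members had been seen to differ. Genes named here were also chosen after their values were seen. The 9 stress-exposed mice were set against the 3 controls in 1 contrast, which called 890 genes, 399 higher and 491 lower, 4 of them the genes listed at 0 in SER. Among genes of sterol synthesis, Hmgcs1 (−0.60 ± 0.08), Msmo1 (−0.73 ± 0.10), Cyp51 (−0.52 ± 0.11), Idi1 (−0.65 ± 0.14) and Sqle (−0.34 ± 0.09) fell, 5 of 21 measured members, and the list median was −0.26 (camera adjusted p = 2.98e-05). The sterol medians of SS mice 19 and 21, −0.08 and −0.02, lay within those of the C mice, −0.11 to 0.14, and the other 7 stress-exposed mice lay between −0.34 and −0.20. A drop of the list beyond that of other genes was not shown, with an adjusted p = 0.536 with an estimated correlation. Glucocorticoid-induced genes had the same adjusted p of 0.536 with an estimated correlation, with 5 of 20 called higher, Hif3a (1.26 ± 0.18), Mertk (0.66 ± 0.10), Zbtb16 (0.60 ± 0.10), Sult1a1 (1.03 ± 0.19) and Plin4 (2.03 ± 0.56), and all 20 positive. The lipid carriers Fabp7 (−1.28 ± 0.17) and Fabp5 (−0.60 ± 0.09) and the myelin gene Opalin (−1.43 ± 0.19) were lower, and the proline-degrading enzyme Prodh (0.57 ± 0.08) higher, with all 9 mice apart from the controls.

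Across the 9 stress-exposed mice, of which 6 also ran, the postsynaptic density list was higher, with a median of 0.27, 5 of 20 called and 17 positive, and an adjusted p = 0.0361 with an estimated correlation. In the running mice alone against C the median was 0.34 (adjusted p = 0.01 with an estimated correlation), and in the sedentary SS mice alone it was 0.18, which did not pass in camera (adjusted p = 0.117; adjusted p = 0.72 with an estimated correlation) but did in fry (adjusted p = 0.00641). After the GC content and length correction it was 0.16 (adjusted p = 0.0156 with the preset and 0.435 with an estimated correlation). All 61 oxidative phosphorylation genes were negative in the 9 stress-exposed mice against C, with 29 called and a median of −0.32. Fry called that list (adjusted p = 0.0361), while camera with an estimated correlation did not (adjusted p = 0.536). The oxidative phosphorylation median was −0.09 after the GC content and length correction.

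Of 100 drawn splits of the 12 libraries into 9 and 3, 2 called as many genes as the real one, itself included (635 genes in a fit of 2 groups), so a count this large was rare among splits. The highest other split called 922 genes and set SS mice 19 and 21 and SES mouse 12 apart, which points to the structure of those libraries. The number was 36 after the GC content and length correction, 195 with the nuclear RNA level as a covariate, and 298 for running mice alone against C. Leaving out 1 mouse gave 8 without C mouse 8, 85 without C mouse 12, 443 without C mouse 2, and 2890, 272 and 435 without SS mice 18, 19 and 21. It gave 532 without SES mouse 10, 264 without SES mouse 12, 376 without SER mouse 6 and 311 without SER mouse 20.

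The median level of 8 nuclear-retained noncoding RNAs against the C mean was 5.52-fold in SS mouse 19, 6.89-fold in SS mouse 21 and 0.725-fold in SS mouse 18, between 1.77-fold and 3.17-fold in SES, and between 0.967-fold and 1.49-fold in SER. The neuropeptide gene Trh stood at 1.315, 22.51 and 22.75 CPM in the SS mice, 12.27, 0.8702 and 13.93 in SES, 12.77, 10.83 and 0.6545 in SER, and at most 1.029 in C. Thalamus markers had medians of 0.92 in C mouse 2 and 0.65 in SS mouse 18 and lay between −0.91 and −0.47 in the other mice.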
